A study of Mus musculus with 15 samples.

How the data were processed

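RNA was measured in 15 libraries, 3 each from secondary MEFs at passage 3, cultures at day 9 of reprogramming, ieCPCs at passages 3 and 12, and CM derivatives. Per the labels' protocols, libraries were made from 10 µg of total RNA and sequenced on an Illumina GAIIx. Reads were aligned with TopHat2 version 2.0.13 to the mouse genome build mm9 and counted per gene with featureCounts of the Subread package, per the submitters' processing notes. The deposited raw count values are whole numbers for 37991 genes, not normalized, per the file headers. The deposited CPM values are counts-per-million over the genes kept by the authors, per the file headers. Values are present for 17925 genes, those between 0.5 and 5000 CPM in at least 2 samples, and empty for 20066. This rule and the empty cells disagreed for 0 genes, and 4 genes were empty because they lie above the ceiling. The columns headed FPKM hold, per the file headers, CPM divided by gene length. That holds for the first MEF library only. In the other 14 libraries the deposited FPKM values equal CPM divided by the raw counts of the preceding library, so they were not used. For Tnnt2 in MEF replicate 2, for example, the deposited FPKM value is 51.8 and CPM over length is 0.796. No per-sample column was left unmapped.

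All tests used the raw counts. Genes with enough counts in a group were kept with filterByExpr of edgeR (4.0.16, with limma 3.58.1 in R 4.3.3), which left 17999 genes. Library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 15 libraries without robust weights. The 5 comparisons were contrasts in this model, tested 2-sided with edgeR's quasi-likelihood F test and adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05, and the words rose, fell and changed refer to such calls. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1, so none is used for single genes. CPM in the text is counts-per-million after TMM scaling. The SE of a log2 fold change is its size divided by the square root of F. For a gene with 0 counts in a group, the fold is a bound that places 3 counts over that group. With 1 to 3 counts it is the ratio with a 95% counting interval where one is given. These intervals and bounds cover counting error only. The common biological coefficient of variation was 0.0679. TMM factors were 0.545 to 0.643 in CM libraries and 0.973 to 1.22 in the others.

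Lists of genes, 26 in all with 651 symbols, were written before the data were examined, together with the leading lists of each comparison, the comparisons, the tests and the naming rule. Of the symbols, 649 matched the table, 15 of them through an older name or gene ID. The list test was camera on the fitted model with a preset correlation of 0.01, 2-sided, adjusted by the Benjamini-Hochberg method over 125 tests. The 4 reprogramming factors gave counts only. Of the 125 tests, 60 passed, and 30 of these passed with an estimated correlation too. Where no p with an estimated correlation follows a passing test, that p was also under 0.05, though often far larger than the printed p. Where no count adjusted over the list alone is given, it equals the count over all genes tested. Genes were named by rule: per comparison the 4 largest rises and 4 largest falls among called genes with at least 10 CPM in the higher group and no overlap of replicates, leaving out predicted or unnamed genes. Names beginning with mmu-mir or with Rn and a digit, and bare gene IDs, were left out too, an extension made after the data were at hand. Further named genes are up to 4 members of each leading list and up to 2 members of any other passing list, called and with at least 1 CPM in the higher group. The reprogramming factors, Kdr and Pdgfra are named throughout. Some genes that the rule names are not reported here. Gene positions are on mm9.

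The procedure was tested on simulated counts of 6 libraries with 200 changed genes per comparison. In the data 36.8% to 65.8% of tested genes changed, so scaling and error rates under that many changes were not tested. At 1.5-fold, 71.6% to 77.6% of the changed genes were recovered over the 5 comparisons, at 2-fold 91.0% to 95.5% and at 4-fold 100%. False calls numbered 9 to 21 among 15233 to 16430 genes. The 21 came in P12 against P3 ieCPCs, beside 52, 64 and 66 genes recovered in order of fold. A simulated 2-fold shift of the Wnt list was called in all 5 comparisons. Of 24 other lists, 2 were falsely called in P12 against P3 and 1 in P3 against day 9. Simulated genes were drawn independently, while the estimated correlation within a list in the data reached 0.578 (sarcomere, CM derivatives against P3). False calls of list tests under such correlation were therefore not tested. Alternatives tried were RLE size factors in edgeR, upper-quartile scaling for counts of changed genes, the tests of DESeq2 (1.42.0) and limma voom, no filter beyond 1 count, and a stricter filter. Also tried were a test against a 2-fold change, an estimated correlation, fry, the replicate number as a block and fits of the 6 compared libraries alone. Each library was left out in turn, and P12 ieCPCs served as another reference for the counts and lists of CM derivatives. Alternatives chosen after the data were seen were upper-quartile scaling for lists and named genes, leaving out mitochondrial genes and other abundant loci, and P12 ieCPCs as the reference for the named genes of CM derivatives. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.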

Results

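RNA sequencing followed mouse fibroblasts through cardiac reprogramming, in 15 libraries that fall into 5 groups of 3. The starting cells were secondary mouse embryonic fibroblasts (MEFs) at passage 3, cells known to carry inducible reprogramming factors from an earlier round of reprogramming. Day 9 cultures had spent 6 days in reprogramming medium, 2 days in transdifferentiation medium and 1 day in the basal medium of the progenitors with BACS, as the labels name it. Induced expandable cardiovascular progenitor cells (ieCPCs) were sorted on day 13 and sampled at passage 3 (P3) and passage 12 (P12). Cardiac derivatives, called CM derivatives in the labels, were ieCPCs held in differentiation medium for 25 days. Library totals ran from 21823056 to 29996464 counts over genes, and 21406 to 23226 genes had at least 1 count in a library. Mitochondrial ribosomal RNA took 18.1% ± 0.0804 of counts in P3 ieCPCs (SD, n = 3) and 46.3% ± 3.27 in CM derivatives. CM replicate 3 stood apart from the others: the chi-square per degree of freedom was 28.8 against replicate 1 and 45.9 against replicate 2, compared with 11.7 between those. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are given as counts-per-million after TMM scaling (CPM), as mean ± SD over 3 libraries.

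**Figure D1:**
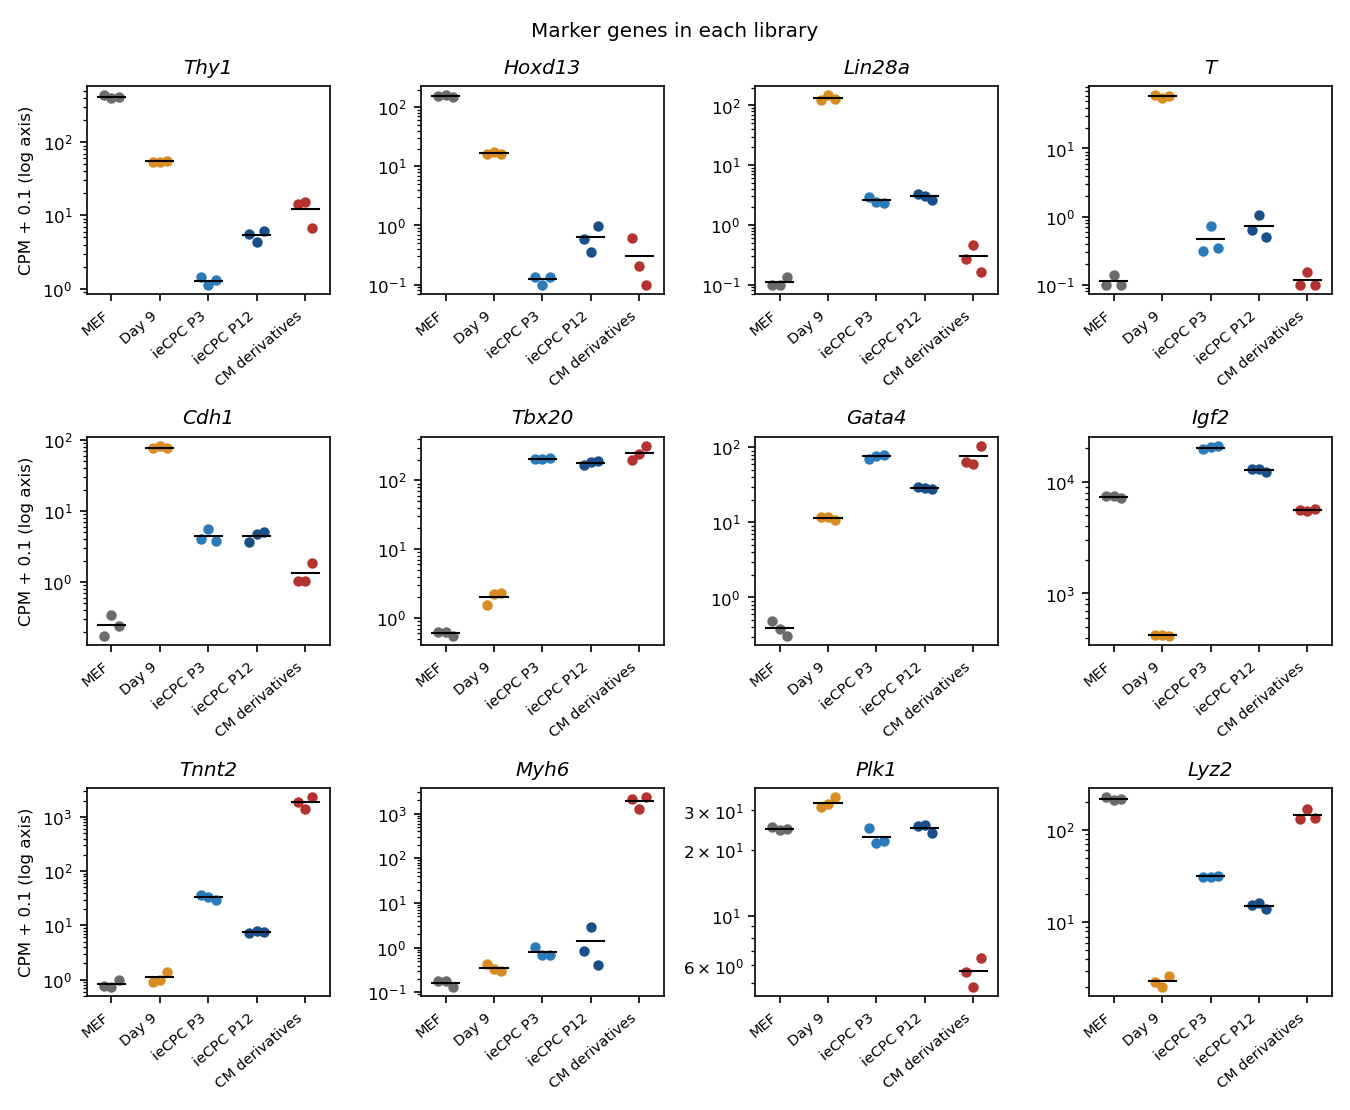
Level of 12 genes in each of the 15 libraries (points; horizontal lines are means of 3 libraries), on a log axis of CPM with 0.1 added; the genes were picked for the plot after their values were seen. Thy1 and Hoxd13 stand highest in MEFs, Lin28a, T and Cdh1 at day 9, and Tnnt2 and Myh6 in CM derivatives, where Myh6 lies between 1244 and 2307 CPM.

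The first comparison asked what 9 days of reprogramming changed in the fibroblasts. By day 9 the cultures carried transcripts of pluripotent cells, of epithelium and of the primitive streak that were close to undetected in MEFs. Lin28a, an RNA-binding protein of stem cells (chromosome 4, 133559245 to 133574756, mm9), rose from 1 count over the 3 MEF libraries to 133 ± 12.33 CPM, a ratio of 10535 (95% counting interval 1890 to 416138). Cer1, a secreted antagonist of Nodal and BMP signals in the early embryo, rose from 0 counts to 80.6 ± 1.75 CPM, at least 2134-fold. The epithelial adhesion protein gene Cdh1 (E-cadherin) rose 497-fold, from 0.152 ± 0.0824 to 77.4 ± 2.88 CPM, with a log2 fold change of 8.96 ± 0.21 (SE). The fibroblast surface marker Thy1 (ENSMUSG00000032011) fell 7.60-fold, from 415 ± 17.9 to 54.5 ± 0.834 CPM. In all, 10289 of 17999 tested genes changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 5349 higher and 4940 lower at day 9. Of these, 2498 were higher and 950 lower by more than 2-fold, and 2077 passed a test against a 2-fold change.

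Among the 4 reprogramming factors, Sox2 rose 12.8-fold to 3.90 ± 0.286 CPM, Pou5f1 rose 8.77-fold to 4.66 ± 0.698 CPM and Klf4 rose 1.63-fold, while Myc fell 1.37-fold. Counts of these genes do not tell transgene from endogenous reads. Of 17 tested pluripotency genes, 15 rose and 2 were not called (camera, adjusted p = 3.27e-41). Besides Lin28a, Tdgf1, a co-receptor for Nodal, rose from 1 count to 71.4 ± 1.61 CPM and the zinc-finger factor gene Sall4 rose 2067-fold to 114 ± 4.12 CPM. The homeobox gene Otx2 rose from 2 counts to 42.8 ± 4.06 CPM, a ratio of 1700 (95% counting interval 470.2 to 14041). The primitive streak and mesoderm list had 21 of 25 genes higher and 3 lower (camera, adjusted p = 1.37e-24). Its T-box factor T (chromosome 17, 8627288 to 8635361) rose from 1 count to 58.2 ± 2.05 CPM, and the streak gene Eomes rose 824-fold to 45.5 ± 0.218 CPM (MEF libraries at 0.0384, 0 and 0.105 CPM). Lhx1, a LIM homeobox gene, rose from 2 counts to 76.8 ± 2.34 CPM. All 20 called genes of the 22 epithelial ones rose (camera, adjusted p = 8.93e-24), among them the splicing regulator Esrp1 by 245-fold (its 4 counts in MEFs all in replicate 2) and the tight-junction gene Ocln from 0 counts, at least 31.6-fold. For these lists the counts adjusted over the list alone were the same.

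Fibroblast and matrix genes went both ways, with 11 of 33 higher and 16 lower, or 17 lower adjusted over the list alone (camera, adjusted p = 0.559). Dcn and Lum, which encode small proteoglycans of the matrix, rose 8.86-fold and 8.50-fold, to 476 ± 12.07 and 479 ± 14.3 CPM. Twist2, a factor of mesenchymal cells, fell 4.07-fold to 2.00 ± 0.346 CPM. Cell cycle genes rose in 34 of 44 cases with none lower, also adjusted over the list alone (camera, adjusted p = 7.44e-05; adjusted p = 0.561 with an estimated correlation). The helicase subunit genes Mcm5 and Mcm3 rose 2.33-fold and 2.12-fold, and the repair gene Ung rose 2.54-fold. Every one of the 18 tested macrophage and blood genes fell (camera, adjusted p = 5.66e-40). The complement genes C1qb and C1qc went from 17.2 ± 1.46 and 11.6 ± 1.87 CPM in MEFs to 0 counts, at least 490-fold and 332-fold lower. Gp49a and Lilrb4 also fell, from 26.7 ± 0.876 and 28.1 ± 1.13 CPM to 1 and 2 counts, but their gene models overlap, so the values are uncertain.

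Wnt targets rose in 17 of 20 cases with none lower (camera, adjusted p = 9.59e-24), including Sp5, from 0 counts to 8.16 ± 0.689 CPM, at least 216-fold. Endoderm and liver genes were higher in 12 of 20 cases and lower in 1 (camera, adjusted p = 9.47e-08), led by the claudin gene Cldn6 (0 counts to 34.8 ± 1.90 CPM, at least 921-fold) and the protease inhibitor gene Spink3 (at least 494-fold). BMP and activin targets had 13 of 23 higher and 6 lower (camera, adjusted p = 0.000838; adjusted p = 0.175 with an estimated correlation), with the Nodal antagonist gene Lefty2 up from 0 counts to 24.0 ± 0.557 CPM, at least 636-fold. FGF and ERK targets had 11 of 21 higher, or 12 adjusted over the list alone, and 5 lower (camera, adjusted p = 0.0234; adjusted p = 0.252 with an estimated correlation), Dusp4 rising 3.06-fold. Mitochondrial and fatty acid oxidation genes had 3 of 31 higher and 19 lower (camera, adjusted p = 0.0151; adjusted p = 0.568 with an estimated correlation), the thiolase gene Acaa2 falling 2.51-fold and the kinase gene Pdk4 rising 4.90-fold. Outside the lists, the largest rises included Trh, the precursor of thyrotropin-releasing hormone, from 0 counts to 47.5 ± 2.00 CPM (at least 1255-fold), Car4 (at least 918-fold) and the homeobox gene Nkx1-2 (at least 782-fold). Kdr and Pdgfra, known as sort markers of the progenitors, measured 12.9 ± 0.641 and 77.0 ± 3.3 CPM at day 9 against 2.82 ± 0.389 and 147 ± 5.98 CPM in MEFs. The remaining 15 lists did not pass the list test. The highest Benjamini-Hochberg adjusted p among the named genes called by edgeR's quasi-likelihood test was 0.0013. Upper-quartile scaling put the median log2 fold change of all genes at 0.12, compared with 0.05 under TMM. With that scaling 6010 genes were called higher and 4255 lower at day 9.

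**Figure D2:**
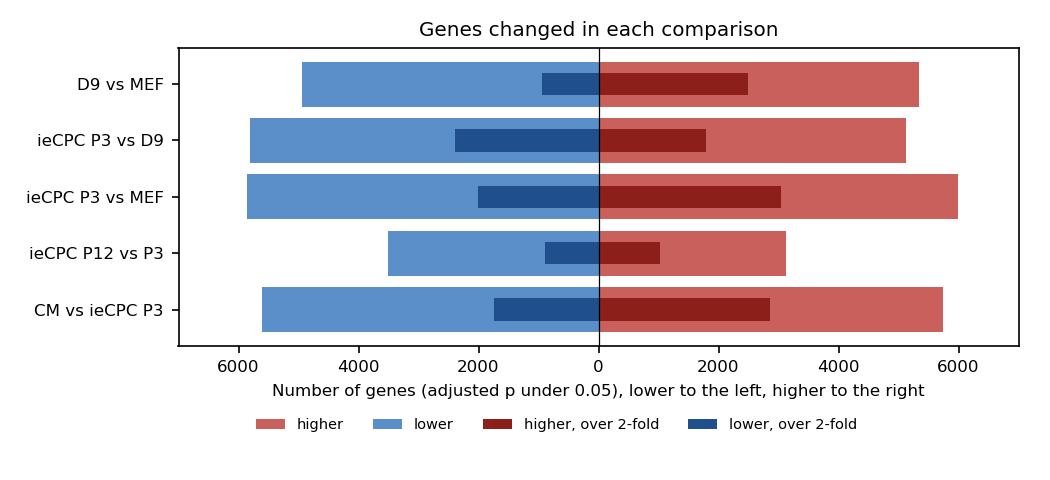
Number of genes that passed the test in each comparison, with genes lower in the first-named group to the left of 0 and higher ones to the right; narrow dark bars count those changed by more than 2-fold. P12 against P3 ieCPCs gave the fewest, 6629, and P3 ieCPCs against MEFs the most, 11844.

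Sorted and expanded P3 ieCPCs were next compared with the day 9 cultures. The streak, pluripotency and epithelial transcripts of day 9 were lower in P3 ieCPCs, while Tbx20, a T-box factor of the developing heart (chromosome 9, 24527648 to 24578746), rose 107-fold from 1.93 ± 0.400 to 205 ± 3.87 CPM. T fell 158-fold to 0.361 ± 0.226 CPM (0.214, 0.621 and 0.247 by library), Lin28a fell 53.4-fold to 2.49 ± 0.350 CPM and Cdh1 fell 17.7-fold to 4.36 ± 0.951 CPM. The largest rise was in Mstn (ENSMUSG00000026100), the gene of the growth inhibitor myostatin, from 0.0576 ± 0.0171 to 415 ± 14.3 CPM, a log2 fold change of 12.68 ± 0.21 (SE). Xist, the RNA that coats an inactive X chromosome (X, 100655714 to 100678556), fell 684-fold, from 196 ± 9.42 to 0.282 ± 0.0971 CPM. By edgeR's quasi-likelihood test 10934 genes changed, 5120 higher and 5814 lower in P3 ieCPCs. More than 2-fold changes numbered 1792 higher and 2389 lower, and 2715 genes passed the test against a 2-fold change.

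Of 34 cardiac transcription factors, 19 were higher and 9 lower, the same adjusted over the list alone (camera, adjusted p = 0.000719; adjusted p = 0.0718 with an estimated correlation). Irx1, a homeobox gene, fell from 3.43 ± 0.418 CPM to 0 counts, at least 98-fold, and its relative Irx3 fell 21.9-fold. Mesp1, a factor of nascent cardiac mesoderm, fell from 2.55 ± 0.742 CPM to 1 count, a ratio of 215 (95% counting interval 38.2 to 8542). Primitive streak and mesoderm genes fell in 21 of 25 cases and rose in 2 (camera, adjusted p = 1.26e-15), among them the mesoderm factor Msgn1, to 0 counts and at least 101-fold lower, and the Notch ligand gene Dll3, 87.4-fold lower. Pluripotency genes fell in 15 of 17 cases and rose in 1, or 2 adjusted over the list alone (camera, adjusted p = 4.44e-14). Tdgf1 fell 68.1-fold, Sall4 45.2-fold and the growth factor gene Fgf4 at least 94.3-fold, to 0 counts. Epithelial genes fell in 20 of 22 cases with none higher, or 1 higher adjusted over the list alone (camera, adjusted p = 6.79e-10), Esrp1 by 24.4-fold and Cldn4 by 32.0-fold. Fibroblast and matrix genes split into 12 higher and 20 lower of 33 (camera, adjusted p = 0.127). Thy1 fell 45.9-fold and S100a4 5.59-fold, whereas the elastin gene Eln rose 7.11-fold to 226 ± 8.06 CPM.

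Hox genes, which specify position along the body axis, fell in 32 of 34 cases and rose in 2 (camera, adjusted p = 8.93e-24). Hoxd13, of the distal limb and posterior trunk, fell from 16.6 ± 0.951 CPM to 2 counts, a ratio of 709 (95% counting interval 196 to 5857), and Hoxc8 fell 294-fold. Imprinted genes were higher in 15 of 24 cases and lower in 8 (camera, adjusted p = 1.33e-20). Igf2, a fetal growth factor gene (chromosome 7, 149836673 to 149852721), rose 47.8-fold to 20247 ± 540.1 CPM, and the zinc-finger gene Plagl1 rose 44.6-fold to 4898 ± 15.8 CPM. Transcripts overlap at the Igf2 locus and the strand setting of the counts is not given, so its value is uncertain. Glycolysis genes fell in 16 of 20 cases and rose in 3 (camera, adjusted p = 2.28e-16, or 0.0166 with an estimated correlation). The enolase gene Eno1 fell by 4.88-fold and the lactate carrier gene Slc16a3 by 7.08-fold. Wnt targets fell in 14 of 20 cases and rose in 4 (camera, adjusted p = 2.42e-08), the caudal homeobox gene Cdx2 reaching 0 counts, at least 66.1-fold lower. Neural genes fell in 11 of 17 cases and rose in 3 (camera, adjusted p = 0.00341), with Stmn2, a microtubule regulator of neurons, 160-fold lower. FGF and ERK targets fell in 18 of 21 cases and rose in 2 (camera, adjusted p = 0.000542; adjusted p = 0.103 with an estimated correlation). The cyclin gene Ccnd1 fell 9.46-fold, from 261 ± 10.5 to 27.6 ± 2.00 CPM.

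Chondrocyte and osteoblast genes rose in 14 of 20 cases and fell in 4 (camera, adjusted p = 3.24e-07; adjusted p = 0.0548 with an estimated correlation). The collagen gene Col9a2 rose 96.0-fold to 40.8 ± 1.51 CPM, and the matrix gene Spp1 fell 108-fold to 0.902 ± 0.0855 CPM. Of 31 p53 and senescence genes, 22 fell and 6 rose (camera, adjusted p = 1.32e-05; adjusted p = 0.132 with an estimated correlation), Hmga1, a chromatin protein gene of proliferating cells, by 19.3-fold and the chemokine gene Ccl2 by 16.9-fold. Sarcomere genes had 14 of 33 higher, or 15 adjusted over the list alone, and 8 lower (camera, adjusted p = 0.0409; adjusted p = 0.777 with an estimated correlation), the cardiac troponin T gene Tnnt2 rising 33.1-fold to 33.0 ± 3.18 CPM and the muscle ubiquitin ligase gene Trim63 rising 128-fold (day 9 libraries at 0.0666, 0.0379 and 0.205 CPM). Endoderm and liver genes had 5 of 20 higher and 10 lower (camera, adjusted p = 0.0309; adjusted p = 0.233 with an estimated correlation), while the fetal serum protein gene Afp went from 3 counts to 2.50 ± 0.619 CPM, a ratio of 71.6 (95% counting interval 24.2 to 349.8). Beyond the lists, the receptor gene Gpr37 rose from 1 count to 12.15 ± 0.454 CPM, Tmem178 rose 269-fold (day 9 libraries at 0.233, 0.114 and 0.0684 CPM) and Art4 rose 145-fold (0.4995, 0.114 and 0.239 CPM), and the chemokine gene Cxcl14 fell from 14.7 ± 0.534 CPM to 2 counts. All of the reprogramming factors fell, Pou5f1 by 4.71-fold, Sox2 by 2.35-fold, Klf4 by 1.42-fold and Myc by 3.14-fold. Kdr and Pdgfra, used for the sort as is known of the study and so no finding, measured 18.2 ± 1.26 and 154 ± 2.89 CPM in P3 ieCPCs. The other 11 lists did not pass. Among the named genes called by edgeR's quasi-likelihood test the highest Benjamini-Hochberg adjusted p was 0.000902.

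Against the starting MEFs, P3 ieCPCs carried far more of several heart-forming factors, and less of the fibroblast marker Thy1 and of macrophage and Hox transcripts. Tbx20 rose 404-fold from 0.505 ± 0.0427 to 205 ± 3.87 CPM, and Gata4, a zinc-finger factor of the early heart (chromosome 14, 63817759 to 63890529), rose 256-fold to 75.4 ± 5.11 CPM. Thy1 fell 349-fold from 415 ± 17.9 to 1.18 ± 0.142 CPM, a log2 fold change of -8.45 ± 0.19 (SE). Hoxd13 (chromosome 2, 74506367 to 74509656) fell from 155 ± 3.33 CPM to 2 counts, a ratio of 6615 (95% counting interval 1831 to 54630). Spp1, the gene of the matrix protein osteopontin, fell 1622-fold from 1471 ± 59.3 CPM. The count of changed genes by edgeR's quasi-likelihood test was 11844, with 5988 higher and 5856 lower in P3 ieCPCs. By more than 2-fold, 3044 were higher and 2014 lower, and 3445 passed the test against a 2-fold change. Upper-quartile scaling called 6553 genes higher and 5372 lower.

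Cardiac transcription factors were higher in 21 of 34 cases and lower in 10, also adjusted over the list alone (camera, adjusted p = 5.16e-05, or 0.0433 with an estimated correlation). Hand1, a factor of lateral mesoderm and heart, rose 35.5-fold to 2.40 ± 0.125 CPM (MEF libraries at 0.153, 0 and 0.0351 CPM), whereas Irx1 fell from 7.42 ± 0.977 CPM to 0 counts, at least 211-fold. Wnt targets rose in 13 of 20 cases, or 14 adjusted over the list alone, and fell in 2 (camera, adjusted p = 0.00651, or 0.0429 with an estimated correlation). The feedback inhibitor Nkd1 rose 15.2-fold and the receptor-like gene Bambi 7.12-fold, while Ccnd1 fell 5.02-fold. Sarcomere genes had 17 of 33 higher and 5 lower (camera, adjusted p = 0.0329; adjusted p = 0.769 with an estimated correlation). With a stricter count filter that list no longer passed (camera, adjusted p = 0.0905, in a range of 0.00189 to 0.769 over its alternatives). Tnnt2 rose 45.02-fold, the troponin I gene Tnni1 rose 32.9-fold to 9.25 ± 0.496 CPM, and the atrial myosin light chain gene Myl7 went from 0 counts to 1.15 ± 0.459 CPM, at least 30.4-fold. Primitive streak and mesoderm genes had 11 of 25 higher and 4 lower (camera, adjusted p = 0.176), Eomes rising 323-fold to 17.8 ± 0.0368 CPM (0.0384, 0 and 0.105 CPM in the MEF libraries) and Osr1 falling 34.4-fold. Fibroblast and matrix genes had 8 of 33 higher, or 9 adjusted over the list alone, and 22 lower (camera, adjusted p = 0.0625). Without MEF replicate 1, 2 or 3 that p was 0.0293, 0.0466 or 0.0402, and it reached 0.0953 with another library left out. With the replicate block it was 0.0278, and with only the 6 compared libraries 0.037. Lum, Eln and Dcn were among the members that rose, by 22.2-fold, 16.7-fold and 12.28-fold.

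The 18 macrophage and blood genes all fell (camera, adjusted p = 2.61e-22), C1qb and C1qc to 0 counts. Hox genes fell in 29 of 34 cases and rose in 2 (camera, adjusted p = 8.93e-24). Imprinted genes rose in 15 of 24 cases and fell in 6 (camera, adjusted p = 8.74e-17), led by Plagl1, 71.9-fold higher, and Phlda2, 25.1-fold higher (0.230, 0.0400 and 0.0702 CPM in the MEF libraries). Glycolysis genes fell in 17 of 20 cases and rose in 3 (camera, adjusted p = 3.11e-16), Eno1 by 6.31-fold. Pluripotency genes were higher in 13 of 17 cases and lower in 1 (camera, adjusted p = 7.41e-06). Among its members, Otx2 went from 2 counts to 25.8 ± 0.567 CPM. Chondrocyte and osteoblast genes rose in 16 of 20 cases and fell in 3 (camera, adjusted p = 1.82e-06; adjusted p = 0.0678 with an estimated correlation), with Col9a2 123-fold higher. Of the p53 and senescence genes 25 of 31 fell and 4 rose (camera, adjusted p = 2.48e-08; adjusted p = 0.0634 with an estimated correlation), but the cell cycle inhibitor Cdkn1c rose 12.32-fold to 423 ± 11.9 CPM.

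Epithelial genes rose in 14 of 22 cases and fell in 1 (camera, adjusted p = 0.0093; adjusted p = 0.211 with an estimated correlation). The desmosome gene Dsp rose 137-fold to 112 ± 2.06 CPM. BMP and activin targets rose in 14 of 23 cases and fell in 4, or 5 adjusted over the list alone (camera, adjusted p = 0.00885; adjusted p = 0.259 with an estimated correlation). Endoderm and liver genes rose in 13 of 20 cases with none lower (camera, adjusted p = 0.0251; adjusted p = 0.295 with an estimated correlation), Cldn6 by at least 95.9-fold. Neural genes had 5 of 17 higher and 6 lower (camera, adjusted p = 0.0207; adjusted p = 0.0678 with an estimated correlation). For that list the test and the mean log2 fold change of -0.75 pointed down while the median was 0.16. Other large rises were in Mstn, 1300-fold with the MEF libraries at 0.0767, 0.0801 and 0.737 CPM, and the muscarinic receptor gene Chrm2, from 2 counts to 21.8 ± 0.262 CPM. Myc fell 4.31-fold and Sox2 rose 5.45-fold, and Pou5f1 rose 1.86-fold to 0.984 ± 0.152 CPM. Without MEF replicate 2 the Pou5f1 call was lost (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0811). Klf4 measured 21.9 ± 1.66 CPM against 19.1 ± 1.40 and was not called, nor was Pdgfra at 154 ± 2.89 against 147 ± 5.98 CPM. Kdr measured 18.2 ± 1.26 CPM against 2.82 ± 0.389 in MEFs. Klf4 was called with only the 6 compared libraries and Pdgfra with upper-quartile scaling (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0177 and 0.0323). In this comparison 11 lists did not pass, and the named genes called by edgeR's quasi-likelihood test had Benjamini-Hochberg adjusted p-values up to 0.0123.

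**Figure D3:**
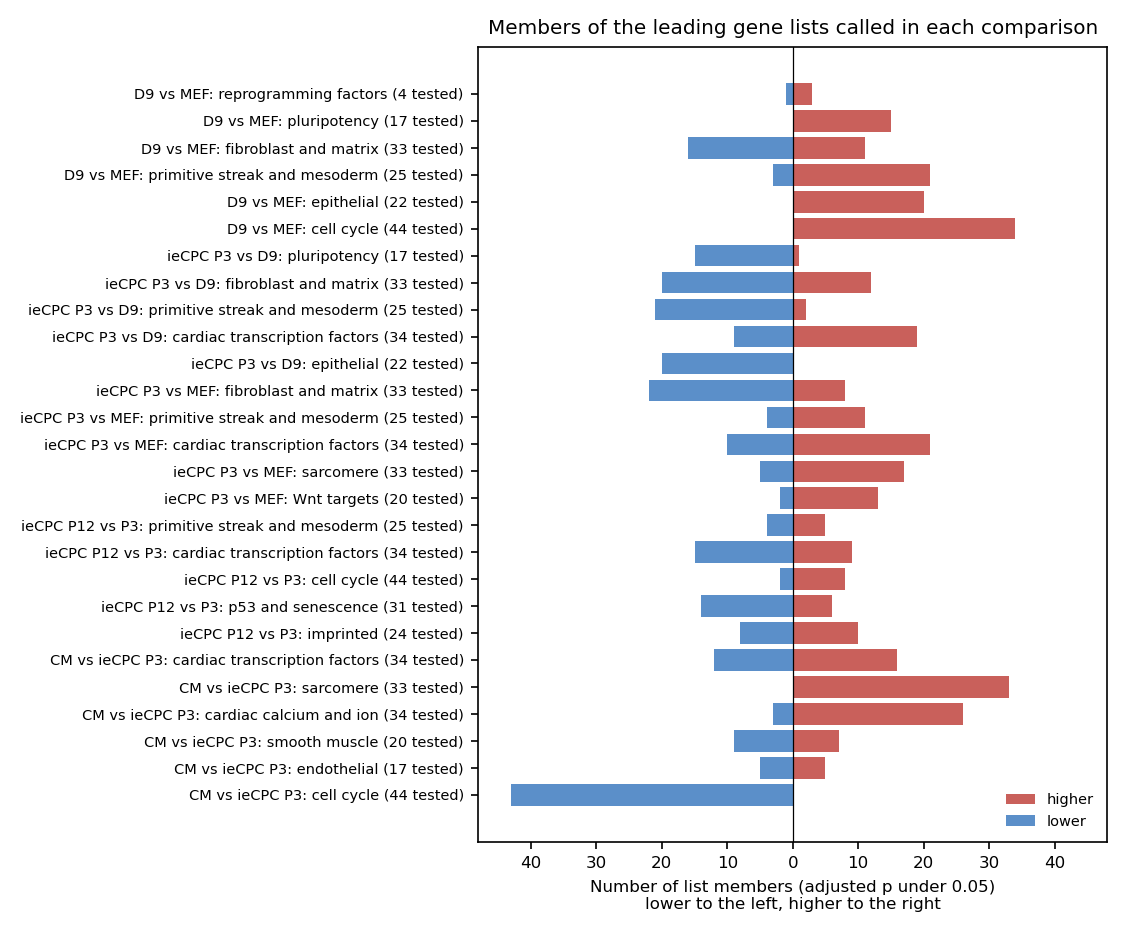
Members of the leading gene lists called lower (left of 0) or higher (right of 0) in each comparison, with the number of tested members in parentheses. In CM derivatives against P3 ieCPCs all 33 sarcomere genes were higher and 43 of 44 cell cycle genes lower; in P12 against P3 ieCPCs each list had members on both sides.

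Early and late passages were compared for the characteristics of ieCPCs during long-term expansion. Cardiac transcription factors moved both ways between P3 and P12. Hand1 (chromosome 11, 57642207 to 57646320) rose 18.98-fold from 2.40 ± 0.125 to 45.7 ± 4.16 CPM and Irx5 rose 16.2-fold, while the epicardial factor Wt1 fell 12.4-fold to 0.669 ± 0.123 CPM and Tbx5, a limb and heart factor, fell 9.85-fold. The ephrin receptor gene Epha3 fell 64.6-fold from 105 ± 3.06 CPM and the adhesion gene Flrt2 (ENSMUSG00000047414) fell 53.2-fold from 204 ± 14.3 CPM, a log2 fold change of -5.73 ± 0.09 (SE). Eif2s3y, a translation factor gene on the Y chromosome (346986 to 365290), fell 26.8-fold from 74.1 ± 3.204 to 2.75 ± 0.241 CPM. The neighbouring imprinted RNAs Meg3, Rian and Mirg of chromosome 12 (from 110779211 to 110987665) fell 122-fold, 24.2-fold and 19.6-fold, Mirg to 0.190, 0.0366 and 0.314 CPM in the 3 libraries. By edgeR's quasi-likelihood test 6629 genes changed, 3122 higher and 3507 lower in P12, and 878 passed the test against a 2-fold change. Upper-quartile scaling turned that split to 3935 higher and 2752 lower. Changes of more than 2-fold numbered 1018 higher and 897 lower.

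No leading list passed the list test between passages. Of 34 cardiac transcription factors 9 were higher and 15 lower, or 10 and 16 adjusted over the list alone (camera, adjusted p = 0.335). Primitive streak and mesoderm genes had 5 of 25 higher and 4 lower (camera, adjusted p = 0.685), Meox1 falling 10.2-fold, Eomes falling 4.29-fold, and Snai1, a factor of epithelial-mesenchymal transition, rising 3.19-fold. Cell cycle genes had 8 of 44 higher and 2 lower, or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.151). With upper-quartile scaling 14 were higher and 1 lower, and with only the 6 compared libraries the list passed (camera, adjusted p = 0.037, in a range of 0.037 to 0.871 over its alternatives). The nucleotide reductase gene Rrm2 rose 1.43-fold and the cyclin gene Ccne1 1.38-fold. Ung fell 1.33-fold, a call lost without P3 replicate 2 or P12 replicate 2 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0703 and 0.1). Of the p53 and senescence genes 6 of 31 were higher and 14 lower, or 8 and 14 adjusted over the list alone (camera, adjusted p = 0.983). Cdkn1c rose 2.88-fold to 1217 ± 37.3 CPM and Igfbp5 rose 2.97-fold. Imprinted genes had 10 of 24 higher, or 11 adjusted over the list alone, and 8 lower (camera, adjusted p = 0.0915). Without P3 replicate 1 or 3 that p was 0.0412 or 0.046, with the test pointing down. The mean log2 fold change of the list was -0.45 and the median 0.09. Overlapping transcripts at Meg3, Rian and Mirg and an unstated strand setting leave their single values uncertain.

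Epicardial and mesothelial genes fell in 12 of 17 cases with none higher, or 14 lower adjusted over the list alone (camera, adjusted p = 1.87e-08). Gpm6a fell 13.5-fold and the uroplakin gene Upk3b 13.0-fold. FGF and ERK targets fell in 15 of 21 cases with none higher, or 16 lower and 2 higher adjusted over the list alone (camera, adjusted p = 9.74e-13). The ERK phosphatase gene Dusp6 fell 3.76-fold to 3.48 ± 0.570 CPM and Dusp4 fell 3.68-fold. Skeletal muscle genes rose in 11 of 19 cases with none lower (camera, adjusted p = 4.77e-06), the embryonic myosin gene Myh3 by 16.4-fold to 15.6 ± 2.42 CPM and the light chain gene Mylpf by 10.4-fold. Wnt targets rose in 10 of 20 cases, or 11 adjusted over the list alone, and fell in 2 (camera, adjusted p = 0.000223), with the Wnt inhibitor gene Wif1 5.72-fold higher and Rnf43 5.35-fold higher. Smooth muscle genes rose in 13 of 20 cases and fell in 3 (camera, adjusted p = 2.33e-05; adjusted p = 0.124 with an estimated correlation). Myh11, the smooth muscle myosin gene, rose 7.76-fold to 82.0 ± 4.38 CPM and the calponin gene Cnn1 rose 4.50-fold. Neural genes had 5 of 17 higher and 4 lower, or 6 and 5 adjusted over the list alone (camera, adjusted p = 0.0201; adjusted p = 0.0678 with an estimated correlation), Stmn2 rising 77.2-fold to 28.4 ± 0.750 CPM.

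Hox genes rose in 13 of 34 cases, or 14 adjusted over the list alone, and fell in 1 (camera, adjusted p = 0.0216; adjusted p = 0.196 with an estimated correlation), Hoxa13 by 5.07-fold to 4.89 ± 0.491 CPM. Glycolysis genes rose in 9 of 20 cases, or 10 adjusted over the list alone, and fell in 4 (camera, adjusted p = 0.0238; adjusted p = 0.474 with an estimated correlation), the glucose carrier gene Slc2a1 by 2.51-fold. Adipocyte genes fell in 4 of 9 cases with none higher (camera, adjusted p = 0.0253; adjusted p = 0.0816 with an estimated correlation), Car3 by 2.93-fold. BMP and activin targets rose in 12 of 23 cases and fell in 7, or 8 adjusted over the list alone (camera, adjusted p = 0.0274; adjusted p = 0.357 with an estimated correlation), the homeobox genes Msx1 and Msx2 by 7.12-fold and 5.33-fold. Fibroblast and matrix genes rose in 18 of 33 cases and fell in 8, or 9 adjusted over the list alone (camera, adjusted p = 0.0493; adjusted p = 0.769 with an estimated correlation), Thy1 by 4.39-fold to 5.23 ± 0.862 CPM. Outside the lists, Odam rose from 3 counts to 18.6 ± 0.981 CPM, a ratio of 528 (95% counting interval 180 to 2563), the tenascin gene Tnn rose 37.6-fold and the protocadherin gene Pcdh9 fell 48.9-fold. AI593442 rose 24.6-fold to 10.2 ± 0.697 CPM. Sox2 fell 4.34-fold and Klf4 fell 1.33-fold. The Klf4 call was lost without P3 replicate 3, P12 replicate 1 or P12 replicate 2 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.076, 0.0611 and 0.069). Pou5f1, Myc and Kdr were not called, at 0.983 ± 0.142, 9.81 ± 0.479 and 19.8 ± 0.663 CPM in P12. Pdgfra, a sort marker like Kdr, measured 269.9 ± 5.45 CPM in P12 against 154 ± 2.89 in P3. All 14 remaining lists, the leading ones included, did not pass, and the named genes called by edgeR's quasi-likelihood test had Benjamini-Hochberg adjusted p-values up to 0.0164.

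The last comparison asked what further cardiac differentiation changed. P3 ieCPCs were the reference because the labels do not give the passage of the parent cells. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty averaged 119, 112, 55.2 and 40.8 CPM in CM derivatives. In P12 ieCPCs they averaged 2.74, 2.75, 2.25 and 1.07 CPM. If most P12 cells had lost these genes, the levels argue against P12 ieCPCs like those sequenced as the parents. Silencing of these genes in P12, which differentiation might undo, was not tested. Heart muscle genes that were close to undetected in P3 ieCPCs were abundant in CM derivatives. Myh6, the alpha cardiac myosin heavy chain gene (chromosome 14, 55560758 to 55585764), rose 2631-fold from 0.716 ± 0.212 to 1893 ± 569.7 CPM, a log2 fold change of 11.36 ± 0.31 (SE). Myl2, of the ventricular light chain (ENSMUSG00000013936), rose from 2 counts to 159 ± 46.3 CPM, a ratio of 6709 (95% counting interval 1857 to 55405). The calcium pump regulator gene Pln rose 461-fold to 505 ± 166.1 CPM. Plk1, a mitotic kinase gene, fell 4.12-fold from 22.7 ± 2.01 to 5.54 ± 0.821 CPM. By edgeR's quasi-likelihood test 11354 genes changed, 5743 higher and 5611 lower in CM derivatives, or 5411 higher and 6024 lower with upper-quartile scaling. Changes of more than 2-fold numbered 2857 higher and 1744 lower, and 2989 genes passed the test against a 2-fold change.

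All 33 tested sarcomere genes rose, also adjusted over the list alone (camera, adjusted p = 5.66e-40, or 0.0264 with an estimated correlation). Myl3 rose 1729-fold to 211 ± 43.7 CPM, and Myh7, the beta myosin heavy chain gene, rose 3930-fold to 388 ± 176.1 CPM. Myh6 and Myh7 are close paralogs and may share reads, so their single values are uncertain. The genes of calcium handling, ion channels and secreted peptides rose in 26 of 34 cases, or 27 adjusted over the list alone, and fell in 3 (camera, adjusted p = 1e-12; adjusted p = 0.163 with an estimated correlation). Trdn, which anchors the calcium release complex, rose 347-fold, the natriuretic peptide gene Nppb rose 263-fold to 13.7 ± 4.92 CPM, and the pump regulator gene Sln went from 0 counts to 4.08 ± 1.95 CPM, at least 114-fold. Levels differed between the CM libraries, with Trdn at 76.9, 55.0 and 142 CPM, Myocd at 21.5, 18.5 and 52.5 CPM and Myh7 at 337, 243 and 584 CPM in replicates 1, 2 and 3. Cell cycle genes fell in 43 of 44 cases, or all 44 adjusted over the list alone (camera, adjusted p = 1.68e-20; adjusted p = 0.124 with an estimated correlation), Kif23 by 3.97-fold and Birc5 by 3.72-fold. Beside these groups, the share of mitochondrial ribosomal RNA was 46.3% ± 3.27 in CM derivatives against 18.1% ± 0.0804 in P3 ieCPCs. Macrophage and blood genes rose in 17 of 18 cases with none lower (camera, adjusted p = 3.14e-10, or 0.0369 with an estimated correlation). Emr1, a macrophage surface gene, went from 0 counts to 8.71 ± 4.64 CPM, at least 254-fold, and Gp49a and Lilrb4, which overlap, rose from 0 counts to 13.9 ± 1.39 and 14.5 ± 2.17 CPM.

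Cardiac transcription factors split into 16 higher and 12 lower of 34 (camera, adjusted p = 0.88). Irx4, a ventricular homeobox factor, went from 0 counts to 4.94 ± 1.14 CPM, at least 139-fold, and Hopx rose 17.5-fold, while the Notch target gene Heyl fell 18.0-fold. Smooth muscle genes had 7 of 20 higher and 9 lower (camera, adjusted p = 0.968), with Mylk 7.16-fold, Myocd 6.85-fold and Des 6.53-fold higher and Notch3 4.24-fold lower. Endothelial genes had 5 of 17 higher and 5 lower (camera, adjusted p = 0.312). Flt1 rose 3.97-fold and Erg fell 10.5-fold from 52.1 ± 1.26 CPM. Kdr, a sort marker of the reference cells and so no finding, was 1.76 ± 0.744 CPM. Mitochondrial and fatty acid oxidation genes rose in all 31 cases (camera, adjusted p = 4.11e-14; adjusted p = 0.0718 with an estimated correlation), the heart and muscle oxidase subunit gene Cox6a2 from 3 counts to 48.5 ± 19.8 CPM and the mitochondrial creatine kinase gene Ckmt2 by 43.5-fold. Imprinted genes fell in 20 of 24 cases, or 21 adjusted over the list alone, and rose in 3 (camera, adjusted p = 2.49e-16), Nnat by 24.3-fold from 197 ± 4.33 CPM and Phlda2 by 14.1-fold to 0.112, 0.367 and 0.122 CPM in the 3 libraries.

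Epicardial and mesothelial genes rose in 13 of 17 cases, or 14 adjusted over the list alone, and fell in 3 (camera, adjusted p = 2e-10), the mesothelin gene Msln by 85.8-fold to 39.5 ± 12.6 CPM and Gpm6a by 28.5-fold. Adipocyte genes rose in 8 of 9 cases and fell in 1 (camera, adjusted p = 4.81e-09), with the fatty acid carrier gene Fabp4 going from 3 counts to 12.7 ± 1.63 CPM and Cd36 rising 41.4-fold. Glycolysis genes rose in 17 of 20 cases and fell in 1 (camera, adjusted p = 4.57e-07; adjusted p = 0.117 with an estimated correlation), the muscle enolase gene Eno3 by 6.24-fold. FGF and ERK targets rose in 15 of 21 cases and fell in 2 (camera, adjusted p = 0.00165; adjusted p = 0.142 with an estimated correlation), Ier3 by 4.80-fold. BMP and activin targets fell in 14 of 23 cases and rose in 2 (camera, adjusted p = 0.00889; adjusted p = 0.252 with an estimated correlation), Hey1 by 11.02-fold. Other large rises included Lcn2, an iron-sequestering lipocalin gene, 3462-fold to 220 ± 23.7 CPM with its 5 counts in P3 ieCPCs all in replicate 2, and the sarcomere protein gene Myoz2, from 1 count to 26.9 ± 11.4 CPM. Large falls included Eomes, 77.4-fold to 0.224, 0.0524 and 0.428 CPM in the 3 libraries, Zcchc12, 126-fold, and Tmem132c, 49.7-fold. Myc rose 2.51-fold, Klf4 rose 1.60-fold and Pdgfra stood at 278 ± 12.8 CPM, higher than in P3 but not called with P12 ieCPCs as the reference (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.483). Sox2 fell 1.76-fold, a call lost without CM replicate 1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.096), and with P12 ieCPCs as the reference its log2 fold change was 1.30. Pou5f1, at 0.817 ± 0.207 CPM, was not called. In this comparison 14 lists did not pass, and the named genes called by edgeR's quasi-likelihood test had Benjamini-Hochberg adjusted p-values up to 0.0118.

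**Figure D4:**
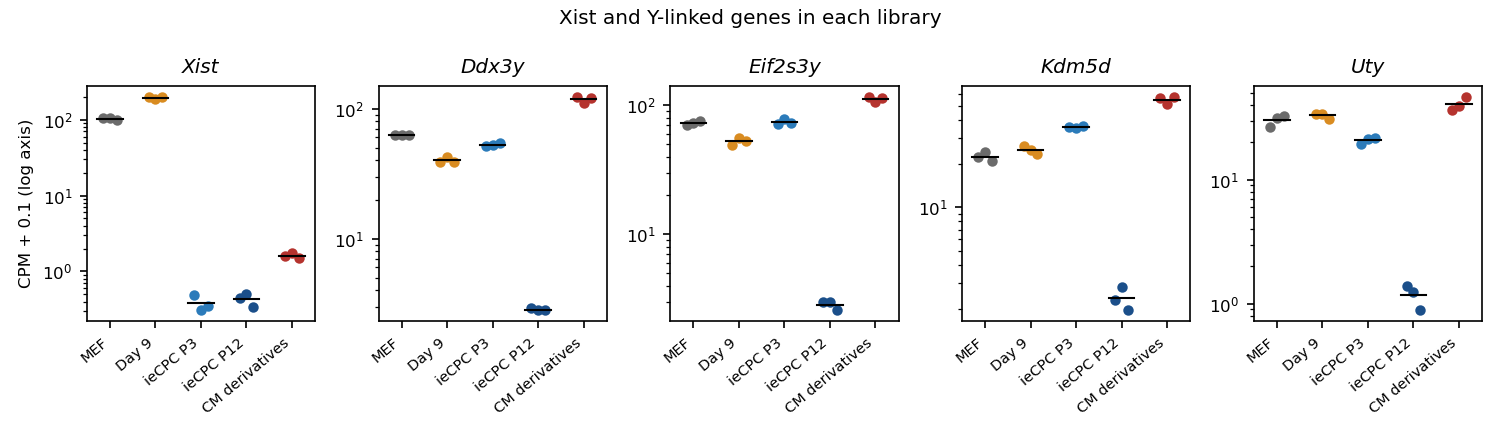
Level of Xist and of 4 Y-linked genes in each library (points; horizontal lines are means of 3 libraries), on log axes of CPM with 0.1 added. Xist lies above 90 CPM in MEFs and at day 9 and under 2 CPM in the later groups, and the Y-linked genes are lowest in P12 ieCPCs, where Ddx3y averages 2.74 CPM.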

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

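Of 81 counts of changed genes under an alternative, 76 stayed within 1.5 times the count reported. The test against a 2-fold change called 2077, 2715, 3445, 878 and 2989 genes in the order of the report. Of 370 tests of leading lists under an alternative, 347 kept their side of the threshold, and of 3065 values of named genes 3054 did. A stricter filter, which tests fewer genes, put the sarcomere list of P3 ieCPCs against MEFs at an adjusted p of 0.0905. Among the leading lists an estimated correlation ended the calls of cell cycle at day 9 (0.561), cardiac transcription factors in P3 against day 9 (0.0718), sarcomere in P3 against MEFs (0.769), and calcium handling (0.163) and cell cycle (0.124) in CM derivatives. The fry test of the leading lists, which asks only whether members move on balance, passed fibroblast and matrix in P3 against day 9 (0.0037) and against MEFs (0.000786) and mesoderm against MEFs (9.46e-08). It also passed cardiac transcription factors (0.00143), mesoderm (0.00894) and imprinted genes (5.63e-06) in P12, all pointing down. In CM derivatives fry passed cardiac transcription factors (0.0198), pointing up, and endothelial genes (9.63e-05), pointing down. The fibroblast list of P3 against MEFs passed with the replicate block (0.0278), with the 6 compared libraries (0.037) and without abundant loci (0.0441, chosen after the data were seen), and ranged from 0.0293 to 0.0953 when libraries were left out in turn. Imprinted genes in P12 ranged from 0.0412 to 0.137 in the same way, and cell cycle in P12 passed with the 6 compared libraries (0.037). With P12 ieCPCs as the reference the log2 fold change of Sox2 in CM derivatives was 1.30 instead of -0.82. Both values come from the same fit, so the change of sign follows from the fall of Sox2 between P3 and P12 given above. The labels share only replicate numbers: 3 of 30 same-numbered pairs correlated over 0.1 (range -0.120 to 0.153), and 5 libraries correlated best with their own number. The replicate block gave 10218, 10910, 11790, 6571 and 11276 changed genes and changed no other call of a leading list. Leaving out libraries ended 7 calls of named genes, those of Pou5f1, Ung, Klf4 and Sox2 given above. In each comparison 1 of the 10 splits of 6 libraries into 3 and 3 called as many genes as the real groups, the real one itself, and the highest count in any other was 0; 10 splits are too few for a share under 0.05.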

Other observations

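Xist and the Y-linked genes were looked at after their values were seen. MEFs and day 9 cultures carried both Xist (104 ± 3.96 and 196 ± 9.42 CPM) and Y-linked transcripts, with Ddx3y at 62.2 and 39.95 CPM. Later groups kept little Xist: 0.282 ± 0.0971 CPM in P3, 0.327 ± 0.0846 in P12 and 1.51 ± 0.109 in CM derivatives. Between MEFs and P3 ieCPCs Xist fell 362-fold, and the median log2 fold change of 678 X-linked genes was 0.30, with 311 higher and 173 lower and autosome medians from -0.09 to 0.11. Between MEFs and day 9, where Xist rose 1.89-fold, the X-linked median was 0.14, with 227 higher and 186 lower and autosome medians from -0.02 to 0.08.

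The tests on Y-linked genes in P12 ieCPCs were chosen after the result was seen, except the one on scaling. Between P3 and P12, Ddx3y fell 19.2-fold to 2.74 ± 0.0602 CPM, Eif2s3y 26.8-fold, Kdm5d 15.7-fold and Uty 19.2-fold, while Usp9y went from 10 counts to 0 and Zfy1 from 13 to 1. A difference in scaling or depth is excluded, since the lowest autosome median was -0.0468, and replacement by cells with an inactive X is excluded, since Xist in P12 was 0.316% of its MEF level. Loss of the Y chromosome from most cells stays open. Of the 5 tested genes with at least 1 CPM in P3, 4 fell. The other, Gm3395, rose from 1.02 to 1.66 CPM (edgeR, adjusted p = 0.0182), or from 87 to 131 counts over the 3 libraries. Loss of the whole chromosome would not give that rise if the reads are from Gm3395. The bound first set, 1 CPM, would have excluded such a loss, and under the bound later raised to 10 CPM this gene decides nothing. The 6 genes that fell lie between positions 61650 and 796225 and Gm3395 at 2550262 to 2552957, so a loss or silencing limited to that stretch and another origin of the Gm3395 reads were not tested.

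For the macrophage genes of CM derivatives, the further list was written before its values were seen and the test on reads crossing between libraries after. Of 19 further macrophage genes, 16 rose, 1 fell (Cd74) and 2 were not called, and Lyz2 measured 31.2 CPM in P3 and 143 in CM derivatives, with Cd68 at 14.4 and Mpeg1 at 13.8. Macrophages or related cells in the cultures would give this, although 3 of 18 genes of the fixed list and 6 of 19 of the further one had at least 1 CPM in the sorted P3 ieCPCs, and 0 of the 19 are in another list. An initial test of reads crossing over from MEF libraries, the median CM to MEF ratio of 0.363, decided nothing. A later one excluded it as the cause: 11 of 3131 transcripts abundant in MEFs lay in CM derivatives under 0.1 of that ratio.

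Both tests on mitochondrial RNA in CM derivatives were chosen after the result was seen. Ribosomal RNA left after selection is excluded as the whole cause of its higher share, since the other mitochondrial transcripts took 16.1% ± 2.42 of counts outside that RNA against 3.29% ± 0.0521 in P3, a ratio of 4.91. More mitochondria per cell would give this, and 31 of 31 genes of the mitochondrial and fatty acid oxidation list rose, or 29 with upper-quartile scaling. That list includes heart and muscle genes such as Cox6a2 and Ckmt2, so its rise cannot tell more mitochondria from a rise of muscle genes. Counts do not measure mitochondria, and a part left after selection stays open.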
